A study of Mus musculus with 2 samples.

How the data were processed

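Sorted CD45+ cells from the cecum, 2 mice per group, were taken from the deposited matrices of a single droplet run, in which each mouse carried its own anti-CD45 hashtag. Per the labels, CTRL 1 carried hashtag 1, CTRL 2 hashtag 3, Trpv1-ADC 1 hashtag 7 and Trpv1-ADC 2 hashtag 9. The deposited expression matrix holds raw UMI counts per gene and barcode, and the deposited hashtag matrix holds raw counts per tag and barcode. Both were found by inspection to be whole numbers. The authors' processing notes name Cell Ranger, Seurat and the mouse build mm10, without versions. Aligner settings, annotation release, how barcodes were chosen and whether hashtag counts are of UMIs or reads were not given in the sources used here, and the labels name both 5' and 3' chemistry.

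The files held 23063 barcodes, 55487 gene symbols, 174231251 UMIs and 17735357 hashtag counts, with 501 to 91135 UMIs per barcode (median 5986). Barcodes with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept (22729). Mice were assigned with HTODemux of Seurat 5.3.0 on the 4 tags the labels name, at a positive quantile of 0.99, which left 18118 singlets after the cell filter. Tag doublets were removed, and Scrublet (scanpy 1.11.5, expected rate 0.2, score threshold 0.357) removed another 1513. Scrublet called 55.5% of tag doublets and 8.35% of tag singlets. The remaining 16605 cells were normalised, reduced to 30 principal components of 2000 variable genes, joined to 15 neighbours and clustered by Leiden (leidenalg 0.10.2) at resolution 1, and T cells and innate lymphocytes again at resolution 1, with seed 0.

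Clusters were named "like" a cell type from 327 markers fixed before the data were examined, as were the 28 gene lists, the tests and most other settings. A cluster with few detected markers, with a low best marker score, or with low depth and none of the markers in front was left unnamed. Germinal centre B cell-like cells and a cluster of unnamed T cells were not compared by name for gene changes. Their leading genes held more markers of another cell type than of their own. Of 25 classes, 18 had at least 20 cells in every mouse, which was the rule fixed beforehand, and 16 of them were tested for genes: non-immune cells, a mix of cell types with 109 to 138 cells per mouse, and unnamed T cells (21 to 41) were left out although the rule gave only the number of cells. Their summed UMIs per mouse ran from 246332 to 5670076, and these totals set the precision of each value.

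The mouse was the replicate. Class shares were tested with the edgeR 4.0.16 quasi-likelihood test on cells per class and mouse, with the Benjamini-Hochberg adjustment over classes and an exact two-sided permutation of mice beside it. For genes, raw counts were summed per mouse and class and tested with edgeR (TMM, filterByExpr, robust quasi-likelihood fit) for Trpv1-ADC against CTRL, adjusted within a class at 0.05. No covariate was used. All log2 fold changes have Trpv1-ADC over CTRL and are given with the SE, and edgeR p values are two-sided. Gene lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values, preset correlation 0.01, adjusted over all lists and classes, and also with an estimated correlation and with fry. With an estimated correlation the degrees of freedom come from the 4 mice alone, so hardly any list could pass. The preset correlation takes the members of a list as nearly independent. Its p values set them against other genes and do not measure the spread between mice. A share of cells with a UMI of 1 gene, fixed beforehand, and values of some named genes are not reported here. Binomial intervals are exact (Clopper-Pearson, 95%) and cover counting error only. A group at 0 was set against a floor of 3 counts over the group.

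Genes are named by a rule fixed before the data were examined. Per class, those past the threshold with both mice of a group apart from both of the other were ranked by log2 fold change, and the 5 largest rises and 5 largest falls were taken, or 10 each for regulatory T cell-like cells and the class with the most cells. Members of the fixed lists past the threshold, up to 4 members per described list by raw p, and 8 genes chosen for regulatory T cells were added. Where fewer than 10 passed, the smallest raw p filled the list as values. Immunoglobulin and T cell receptor segments were counted and not named. Of the genes the rule gave, the text describes a part.

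The procedure was tested on simulated data with 200 genes changed per class. At 4-fold 81.4% to 98.4% of those tested were called, at 2-fold 24.2% to 66.1% and at 1.5-fold 1.49% to 26.2%, with 0 to 9 false calls. A tripled class share was called in 94 of 100 draws, with 48 calls in 2400 tests of the other classes. Smaller changes in share were not drawn. How often they would be called is not known, such as 12.3% in CTRL against 5.32% in Trpv1-ADC mice for intraepithelial-type T cell-like cells. The draws set a spread between mice of 0.15 in natural log. Some classes varied more, such as CD4 T cell-like cells (2.44% of CTRL 1 and 8.45% of CTRL 2). Alternatives were DESeq2 1.42.0 and its size factors in edgeR, no low-count filter, a fit that was not robust, immunoglobulin genes left out, mouse number as a block, cells drawn down to equal numbers, a tag rule (top tag at least 10 counts and 3 times the next), a stricter cell filter (1000 UMIs, 500 genes, 5% mitochondrial), no Scrublet, Leiden resolution 2, other denominators and each mouse left out. Leaving a mouse out leaves 1 in its group, which is assumed to vary like the other group. Clustering without interferon, heat shock and immediate early genes, leaving naive cells out of a denominator, and tests within single clusters were added after seeing the data. Other software was R 4.3.3, Python 3.11.15, scikit-learn 1.9.0, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. Hashtags that the labels assign to no mouse were left out of all comparisons.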

Results

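The study's title asks whether Trpv1+ nociceptors, pain-sensing neurons that carry the capsaicin-gated channel Trpv1, act on regulatory T cells of the gut. CD45+ immune cells were sorted from the cecum of 2 CTRL and 2 Trpv1-ADC male mice, 101 days old, in which Trpv1+ neurons were to be activated in the latter. The labels name the strains Trpv1-WT.B6 and Trpv1-Cre.B6 without saying which mouse was which, so the groups may also differ in strain. Per the labels, AAV had been injected at birth and CNO, the ligand of designer receptors, had been given 7 times on alternate days. The mice carried separate DNA-coded tags on CD45 and went through 1 droplet run, so that the run did not differ between the groups. After filtering, 16605 cells remained: 3848 from CTRL 1, 3975 from CTRL 2, 4358 from Trpv1-ADC 1 and 4424 from Trpv1-ADC 2. Their total counts were 24818614, 26246308, 27201293 and 28697329 UMIs, and the median depth per cell lay between 5520 and 5649.5 UMIs in every mouse. The mouse was the replicate throughout (n = 2 per group), numbers only name the mice, and the smallest permutation p this design allows is 0.333.

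Among the classes of sorted cells, the largest differences in percentage points were in T cells. Intraepithelial-type T cell-like cells, named from Gzma, Cd160, Itgae and related markers of lymphocytes lodged in the gut lining, formed 12.3% ± 2.12 of the cells of CTRL mice and 5.32% ± 1.14 of those of Trpv1-ADC mice (SD, n = 2). Naive CD8 T cell-like cells formed 10.997% ± 1.46 and 18.5% ± 3.27, and naive CD4 T cell-like cells 15.3% ± 2.83 and 20.7% ± 1.57. Of the myeloid classes, monocyte-like cells held 4.60% ± 1.03 against 2.35% ± 0.476, and neutrophil-like cells 0.859% ± 0.182 against 0.342% ± 0.00363. Plasma cell-like cells, the antibody-secreting cells, held 1.06% ± 0.00628 against 0.491% ± 0.215. B cell-like cells stood at 15.02% ± 2.02 and 15.9% ± 2.79. ILC3-like cells, innate lymphocytes that make interleukin 22, held 1.70% ± 0.160 and 2.29% ± 0.0884.

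None of the 25 classes passed the test of the shares: edgeR called 0 after adjustment (lowest adjusted p = 0.148), 5 had a raw p under 0.05, and 15 had their 2 groups apart, which gives the smallest permutation p of 0.333. In log2 fold change the edgeR values were -1.20 ± 0.34 (SE) for intraepithelial-type, -0.97 ± 0.30 for monocyte-like, -1.32 ± 0.43 for neutrophil-like, 0.75 ± 0.26 for naive CD8 and -1.11 ± 0.42 for plasma cell-like cells. With only tag doublets removed, edgeR called 7 classes, intraepithelial-type (-1.19), monocyte-like (-0.71), neutrophil-like (-1.54), naive CD8 (0.74), ILC3-like (0.46), natural killer cell or ILC1-like (-0.56) and mixed effector T cells (-0.41). A stricter cell filter called 2, intraepithelial-type (-1.23) and monocyte-like (-0.96). Mouse number as a block called 4, monocyte-like (-0.97), mixed effector T cells (-0.53), ILC3-like (0.43) and an unnamed cluster of low-depth cells (-1.97). Without CTRL 1 edgeR called conventional dendritic cells of type 1 (-0.79), and without Trpv1-ADC 1 the unnamed cluster (-3.45). At Leiden resolution 2 the monocyte-like value was its weakest, -0.55 ± 0.28 (edgeR adjusted p = 0.256), while the intraepithelial-type value was -1.22. Shares are of CD45-sorted cells, so the shares of cells that carry little CD45 depend on the sort and are not those of the tissue. Fibroblasts, endothelium and other non-immune cells were 3.33% in CTRL and 2.57% in Trpv1-ADC mice.

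**Figure D1:**
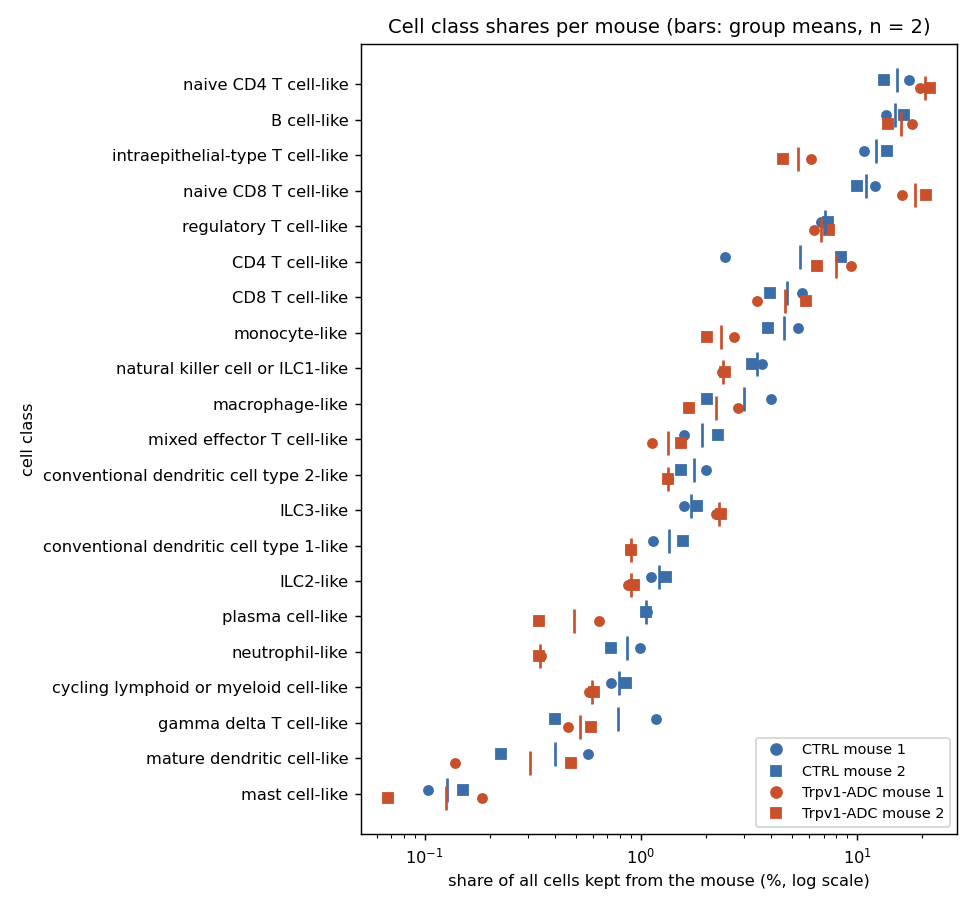
Share of each cell class among the cells kept from each mouse, in percent on a log axis, with vertical bars at the group means (n = 2 mice per group). Intraepithelial-type T cell-like cells averaged 12.3% in CTRL and 5.32% in Trpv1-ADC mice, and naive CD8 T cell-like cells 10.997% and 18.5%.

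Regulatory T cell-like cells, which restrain immune responses and are marked by the transcription factor Foxp3, formed 25.5% ± 0.335 of CD4 T cells in CTRL mice and 19.3% ± 2.02 in Trpv1-ADC mice (SD, n = 2). CD4 T cells here are the naive CD4, CD4 and regulatory T cell-like classes together. The share was 25.7% in CTRL 1 (exact 95% binomial interval 23.1 to 28.5, 1022 cells) and 25.3% in CTRL 2 (22.8 to 27.9, 1156 cells). It was 17.8% in Trpv1-ADC 1 (15.9 to 19.8, 1537 cells) and 20.7% in Trpv1-ADC 2 (18.7 to 22.8, 1581 cells), intervals that cover counting error only. The difference of -6.24 points gave an exact two-sided permutation p of 0.333, the smallest possible. Over all cells kept, the class held 7.09% ± 0.361 and 6.84% ± 0.781, while the naive CD4 class in the denominator was the larger in Trpv1-ADC mice. Over all T cells the difference was -1.65 points, and for T cells with a Foxp3 UMI over all T cells -1.58 points (8.63% against 7.05%). With naive cells left out of the denominator, a choice made after seeing the data, it was -13.6 points (60.1% ± 19.2 against 46.5% ± 9.15, permutation p = 0.667).

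In regulatory T cell-like cells of Trpv1-ADC mice Il10, the anti-inflammatory cytokine and 1 of the markers that named the class, fell by 0.61 ± 0.11 on the log2 scale (edgeR adjusted p = 0.00305), from 733 and 855 CPM in CTRL 1 and CTRL 2 to 585 and 465 in Trpv1-ADC 1 and Trpv1-ADC 2. Areg, the tissue repair factor amphiregulin, fell by 0.61 ± 0.12 (adjusted p = 0.00676), Ccr2, a chemokine receptor of inflamed tissue, by 0.80 ± 0.13 (7.81e-04), and S100a4, a calcium-binding protein of activated T cells, by 0.78 ± 0.14 (0.0067). Lmna, a nuclear lamin, fell by 1.71 ± 0.24 (0.014), the AP-1 subunit Fosb by 0.67 ± 0.10 (2.89e-04) and the gelatinase Mmp9 by 1.017 ± 0.21 (0.00782). Ccl5, Crem and Il2rb fell too, by 0.84, 0.46 and 0.46. Transcripts that rose included Tcf7, the factor of naive and central T cells, by 0.53 ± 0.13 (0.0366), Nr4a2, induced by antigen receptor signals, by 0.75 ± 0.15 (0.0061), the granule protein gene Nkg7 by 0.95 and Izumo1r, the folate receptor 4 gene, by 0.44. Larger rises were in Cntn5 (1.82), a neural adhesion gene, Pgpep1l (1.49), Dnase1l3 (1.40) and the non-coding AA465934 (3.33). Foxp3 itself did not pass at -0.39 ± 0.11 (0.096), nor did Ctla4 (-0.26, 0.279), Ikzf2 (0.22, 0.43) or Gata3 (-0.26, 0.69). Receptor components of the neuropeptide CGRP, Calcrl (0.50, 0.452) and Ramp1 (-0.16, 0.88), did not pass either.

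In all, edgeR called 114 of 9278 genes in regulatory T cell-like cells, 50 higher and 64 lower (957 at raw p under 0.05). The fixed list of 40 regulatory T cell genes fell as a group by camera (median log2 fold change -0.23, adjusted p = 1.17e-05): 1 member rose and 5 fell, or 2 and 11 when adjusted over the list alone. Its adjusted p was 0.85 with an estimated correlation, as was that of ribosomal protein genes, a list that tracks RNA quality, which rose (median 0.17, adjusted p = 7.87e-10). The 14 heat shock genes rose as a list beside them (median 0.27, adjusted p = 6.27e-05, 0.85 with an estimated correlation, 0.131 without CTRL 1 and 0.0637 without Trpv1-ADC 2), with 0 members past the test over all genes and 2 adjusted over the list alone. The largest of its 4 clusters was T9 in CTRL mice (41.8%, against 24.5%) and T8 in Trpv1-ADC mice (39.1%, against 26.7%), and Hspa1a was high in T9. Within T8 alone Il10 stood at -0.44 (adjusted p = 0.227) and within T9 alone at -0.39 (0.259), tests added after the class result. Ccr2 was -1.06 in T8 (0.00289) and -0.10 in T9, and S100a4 -0.41 in T8 and -0.03 in T9. Fosb was 0.28 in T8 and -0.82 in T9 (0.00828). The call of Il10 was lost without CTRL 2 (adjusted p = 0.0678), that of Areg without CTRL 2 (0.274) or Trpv1-ADC 2 (0.0833), and those of Nr4a2 and Mmp9 without Trpv1-ADC 2 (0.161 and 0.22). Dnase1l3 was lost without Trpv1-ADC 2 (0.381), and Lmna without Trpv1-ADC 1 (0.23) or Trpv1-ADC 2 (0.407). Tcf7, Nkg7, Izumo1r, Ccl5 and Crem were lost without CTRL 1 (0.254 for Crem to 0.475 for Izumo1r) and without either Trpv1-ADC mouse, and Il2rb without CTRL 2 (0.392) or either Trpv1-ADC mouse. Calls of AA465934, Ccr2, Cntn5, Fosb, Pgpep1l and S100a4 stood in all 4 fits that left out a mouse. The class count was 65 without Trpv1-ADC 2, 32 with DESeq2, 43 with the ratio rule for tags, 33 with the stricter cell filter, and 36, 32, 15 and 0 in clusters T8, T9, T13 and T14 alone.

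**Figure D2:**
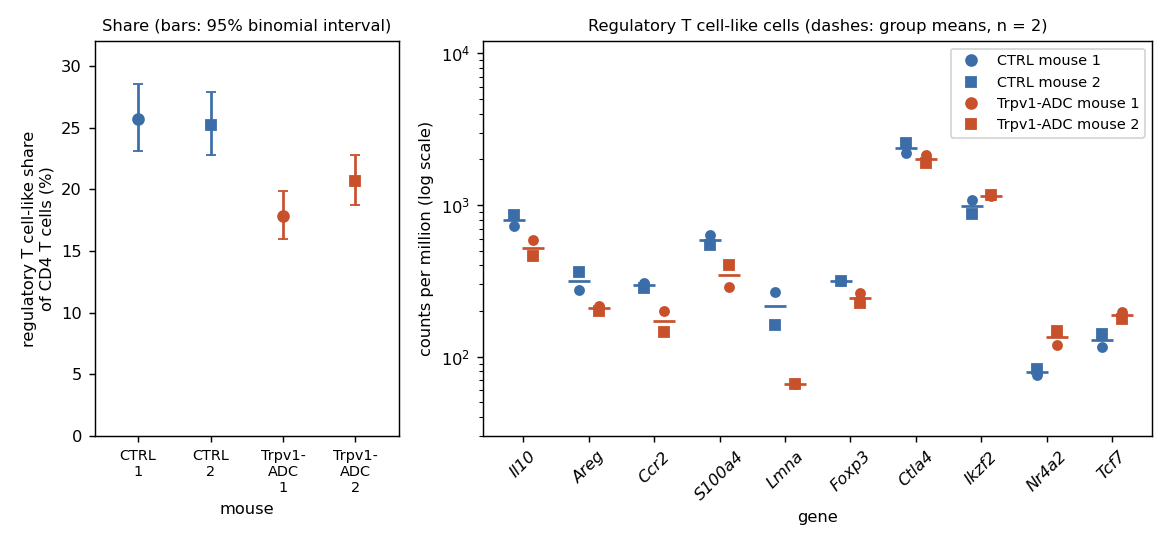
Regulatory T cell-like share of CD4 T cells per mouse, in percent with exact 95% binomial intervals, and CPM (normalised counts) of 10 genes in that class per mouse on a log axis, with dashes at the group means (n = 2 per group). Il10 lay at 733 and 855 CPM in the CTRL mice and at 585 and 465 in the Trpv1-ADC mice. Foxp3, Ctla4 and Ikzf2 did not pass the test.

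Intraepithelial-type T cell-like cells showed the most called genes of the 16 classes tested, 462 higher and 466 lower of 10081 (2444 at raw p under 0.05). Gzmb, the cytotoxic protease granzyme B and a marker of the class, fell by 0.73 ± 0.14 in log2 (edgeR adjusted p = 0.00475). Gzmb was a leading gene of cluster T7, which held 36.6% of the class in CTRL and 26.8% in Trpv1-ADC mice. The class value alone does not separate a fall within cells from this shift. Serpinb9, the inhibitor of granzyme B, fell by 1.34 ± 0.15 (1.58e-04) and the AP-1 subunit Fosl2 by 1.42 ± 0.18 (0.00115). Nr4a3 fell by 1.05 ± 0.20 (0.0127), and Tnfaip3, a brake on NF-kB, by 0.98 ± 0.18 (0.0122). Cytokine receptor and signal genes Il21r (-0.97), Stat4 (-0.87), Socs1 (-0.88) and Bhlhe40 (-0.97) fell, as did the repressor Bach2 (-0.92). Stat3 fell by 0.79 and the unfolded protein response factor Xbp1 by 0.92. Of the cell cycle genes, Cenpa fell by 1.53 and Hmgb2 by 0.92. Ltb, which encodes lymphotoxin beta, rose by 0.95 ± 0.14 (0.00138), P2rx7, the ATP-gated channel, by 0.91, Jun by 1.024 ± 0.11 (1.36e-04), the type 2 regulator Gata3 by 0.77, Csf2, the cytokine GM-CSF, by 1.68, and the interferon-induced Oasl1 by 2.04. Lif, a cytokine with no count in the CTRL mice, was at least 14.2-fold higher against a floor of 3 counts over the group (20 counts).

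Among 24 cAMP and CREB response genes of the intraepithelial-type class, 1 rose and 7 fell, or 2 and 9 adjusted over the list alone. The list fell by camera (median -0.34, adjusted p = 0.00155, and 0.85 with an estimated correlation). Crem, a cAMP-induced transcription factor, fell by 1.05 ± 0.15, the phosphodiesterases Pde10a and Pde4d, which break down cAMP, by 1.99 and 0.84, and Ramp3, part of adrenomedullin and CGRP receptors, by 1.29 ± 0.18 (7.7e-04). Of 14 heat shock genes, 4 rose and 1 fell, 5 and 1 adjusted over the list alone (median 0.20, adjusted p = 0.0292, 0.882 with an estimated correlation, 0.0748 without CTRL 1 and 0.851, downwards, without Trpv1-ADC 1). Bag3 rose by 1.73 and Hspa1a by 0.63, and Hspa5, a chaperone of the endoplasmic reticulum, fell by 0.67. Crem fell in cluster T4 alone (-1.13, adjusted p = 0.00276) and in T7 alone (-0.88, 0.0266), Serpinb9 (-1.32 and -1.07) and Ramp3 (-1.33 and -1.42) likewise. Clusters T4 and T7 held 63.4% and 36.6% of the class in CTRL mice, 73.2% and 26.8% in Trpv1-ADC mice, and called 528 and 181 genes. Gata3, Stat3 and Hspa5 lost their calls without CTRL 2 (adjusted p = 0.11, 0.0537 and 0.14), Csf2 and Xbp1 without CTRL 1 (0.0874 and 0.0582), and Lif without CTRL 2 (0.0607). Lif was not tested without either Trpv1-ADC mouse. The class count was 427 without CTRL 1, 368 without CTRL 2, 1282 without Trpv1-ADC 1 and 1017 without Trpv1-ADC 2, 306 with DESeq2, and 482 with cells drawn down to equal numbers.

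In macrophage-like cells of Trpv1-ADC mice Clec4e, a receptor for microbial glycolipids, fell by 1.81 ± 0.25 in log2 (edgeR adjusted p = 0.00588), Nlrp3, the inflammasome sensor, by 1.41 ± 0.22 (0.00945), and Il1b, the cytokine it releases, by 0.92 ± 0.21 (0.0455). The chemokine genes Ccl2 and Cxcl1, which draw monocytes and neutrophils, fell by 1.29 and 1.82, and Cd80, a co-stimulator of T cells, by 1.69. Klf4 (-1.51), Nfil3 (-1.32) and the cAMP phosphodiesterase Pde4b (-1.63) fell, and so did Wnt11 (-2.90). Ciita, the master regulator of MHC class II, rose by 1.18 and Ly6c2 by 2.91. Ly6c2 was fixed as a monocyte marker, but here it was a leading gene of the CD8 T cell-like cluster T5. Il10 fell by 0.91 ± 0.21 (0.0477), a call lost in each fit that left out a mouse (0.0585 to 0.114). Ccl5 rose by 1.82, yet lay at -0.16 at Leiden resolution 2 and at -0.014 with only tag doublets removed.

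Among 21 inflammatory myeloid genes of macrophage-like cells, 1 rose and 8 fell, 1 and 12 adjusted over the list alone (median -0.78, adjusted p = 2.08e-07). Of 23 cAMP and CREB response genes, 0 rose and 5 fell, 0 and 11 adjusted over the list alone (median -0.64, 4.19e-09), and of 22 immediate early genes 0 rose and 4 fell, 0 and 8 adjusted over the list alone (median -0.65, 3.53e-09). Each of these 3 lists had an adjusted p of 0.85 with an estimated correlation. Ribosomal protein genes rose as a list (median 0.29, adjusted p = 1.26e-04, 0.852 with an estimated correlation and 0.114 without Trpv1-ADC 2). Heat shock genes rose as a list (median 0.29, adjusted p = 0.0119, 0.852 with an estimated correlation and 0.607 without Trpv1-ADC 1). In all, 34 genes were higher and 135 lower of 8149 (1261 at raw p under 0.05). Cluster A11 held 67.9% of the class in CTRL and 86.7% in Trpv1-ADC mice, and A22, marked by Retnla and Fn1, 32.1% and 13.3%. A11 alone called 1 gene, with Nlrp3 at -1.64 and Il1b at -1.14, not past the test there. Il1b, Ccl2, Cxcl1 and Cd80 lost their calls without CTRL 1 (adjusted p = 0.209, 0.0948, 0.0622 and 0.0557). The count was 101 without CTRL 1, 263 without CTRL 2, 512 without Trpv1-ADC 1 and 322 without Trpv1-ADC 2, 113 with DESeq2, 88 at Leiden resolution 2, 89 with cells drawn down, 103 with the ratio rule for tags, 79 without robust fitting, 409 with mouse number as a block and 428 without the low-count filter.

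In monocyte-like cells of Trpv1-ADC mice Atf3, a stress-induced repressor, rose by 1.04 ± 0.15 (edgeR adjusted p = 9.8e-04), Lcn2, the iron-withholding lipocalin, by 3.14 ± 0.48 (0.00111), Hspa1b by 1.29 ± 0.14 (1.41e-04), and Klf2 and the chemokine gene Ccl3 by 0.86 and 1.06. Thbs1, a matrix glycoprotein among the leading genes of this cluster, fell by 1.04 ± 0.17 (0.00501), Areg by 2.04 ± 0.37, the ATP-degrading Entpd1 by 0.93 and the maturation marker Cd83 by 0.71. Of 14 heat shock genes 8 rose, 12 rose and 1 fell adjusted over the list alone (median 0.74, adjusted p = 1.22e-14). Of 23 type I interferon genes 3 rose, 5 adjusted over the list alone (median 0.62, 1.38e-08), among them Slfn1 (1.06) and Trim30a (0.73). Of 14 MHC class II genes 1 rose and 2 fell, 1 and 6 adjusted over the list alone (median -0.33, 0.00456), with H2-Eb1 at -0.47 and H2-DMb1 at -0.67. Ribosomal protein genes rose as a list (median 0.25, 1.36e-06). These 4 lists had an adjusted p of 0.85 with an estimated correlation, and the interferon list lost its call without CTRL 1 (camera adjusted p = 0.151). Together 51 genes were higher and 67 lower of 7843 (1004 at raw p under 0.05). Areg and Cd83 lost their calls without CTRL 1 (adjusted p = 0.183 and 0.196), Klf2, Ccl3 and Entpd1 without CTRL 2 (0.0517, 0.0867 and 0.0642), Trim30a without CTRL 1 (0.505) or Trpv1-ADC 2 (0.186), and Slfn1, H2-Eb1 and H2-DMb1 without any mouse but Trpv1-ADC 1 (for H2-Eb1 0.261, 0.473 and 0.186). The count was 37 without CTRL 1, 81 without CTRL 2 and 286 without Trpv1-ADC 1, 88 with DESeq2, 401 at Leiden resolution 2, 50 with cells drawn down, 53 with only tag doublets removed, 50 without robust fitting, 180 with mouse number as a block and 248 without the low-count filter.

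Conventional dendritic cells prime T cells, those of type 1 mainly CD8 T cells. In type 1-like cells of Trpv1-ADC mice Cd80, a co-stimulator, fell by 1.37 ± 0.22 (edgeR adjusted p = 0.00432), Cd83 by 0.87, Nr4a2 by 1.18 ± 0.18 (0.00432), Egr3 by 1.55 and the chemokine gene Cxcl2 by 1.36. The chaperone genes Hspa5 and Dnajb14 fell by 0.75 and 2.31, while Hspa1a rose by 1.68 ± 0.13 (2.44e-06), Jun by 1.501, Areg by 2.43 ± 0.47 (0.026) and Tnfsf15, a T cell co-stimulator, by 4.41. Of 13 cell cycle genes 2 fell, Top2a and Stmn1, also 2 adjusted over the list alone (list median -0.79, adjusted p = 7.08e-08, and 0.85 with an estimated correlation). Both lost their calls without CTRL 2 (0.509 and 0.166), and Stmn1 also without Trpv1-ADC 2 (0.119). Type 2-like cells had Clec7a, the beta-glucan receptor and a leading gene of that cluster, lower by 0.98 ± 0.13 (0.00535). Lef1, a factor of naive T cells, rose by 2.64, the junction gene F11r by 1.89, Hspa1b by 1.52 and Hsp90aa1 by 1.01. Heat shock genes rose as a list in both (medians 0.73 and 1.10, adjusted p = 0.85 with an estimated correlation), with 3 higher and 1 lower in type 1 and 5 higher in type 2, 8 and 1 against 13 and 1 adjusted over the list alone. The type 1-like count was 20 higher and 35 lower of 6539 (707 at raw p under 0.05), and type 2-like cells had 9 and 1 of 6763 (486). Without CTRL 1, CTRL 2, Trpv1-ADC 1 and Trpv1-ADC 2 these became 136, 183, 201 and 119 for type 1 and 90, 33, 33 and 41 for type 2. Cd83 in type 1 lost its call without Trpv1-ADC 2 (0.0952).

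In ILC3-like cells Areg fell by 1.80 ± 0.29 (edgeR adjusted p = 0.00752), Ramp3 by 1.18 ± 0.18 (0.00519), Pde10a by 1.45 ± 0.25 (0.0125) and Il12rb2, a subunit of the interleukin 12 receptor, by 1.19 ± 0.22 (0.0154). Bhlhe40 and Nfkbid fell by 0.78 and 1.36. Heat shock genes Bag3, Hspb1 and Hspe1 rose by 2.21, 2.53 and 1.15, 6 of 14 in all and 12 adjusted over the list alone (median 0.95, adjusted p = 5.47e-20, and 0.85 with an estimated correlation). The ILC3-like count was 20 higher and 20 lower of 6830 (735 at raw p under 0.05), becoming 107, 159, 131 and 101 without CTRL 1, CTRL 2, Trpv1-ADC 1 and Trpv1-ADC 2. Bhlhe40 and Nfkbid lost their calls without Trpv1-ADC 2 (0.463 and 0.12). In ILC2-like cells, which make type 2 cytokines, edgeR called 0 of 4382 genes within the class (276 at raw p under 0.05, DESeq2 1), and 4 when adjusted over all classes together. Those 4 were lower: the cytokine Il5 by 1.76 ± 0.32 (0.223 within the class, 0.0351 over all classes), the interleukin 33 receptor Il1rl1 by 1.57 ± 0.25 (0.18 and 0.022), Stab2 by 1.70 (0.107 and 0.00997), these 3 leading genes of the cluster, and Pcsk1 by 3.28 (0.18 and 0.0265). The Notch target Hes1 stood at 0.88 ± 0.18 (0.272). As a list, heat shock genes rose (median 0.40, adjusted p = 0.00252, 0.85 with an estimated correlation and 0.874 without Trpv1-ADC 2). Counts there were 19, 40, 58 and 42 without CTRL 1, CTRL 2, Trpv1-ADC 1 and Trpv1-ADC 2. Natural killer cell or ILC1-like cells had 7 genes higher and 1 lower of 7354 (712 at raw p under 0.05): Dnajb1 rose by 1.72 ± 0.20 (0.018), Hsph1 by 1.46, Hspe1 by 1.16 and Jun by 1.27, and Camk4, a calcium-dependent kinase, fell by 0.76 ± 0.11 (0.0421). Of 14 heat shock genes 4 rose, 11 adjusted over the list alone (median 1.06, adjusted p = 7.56e-20, and 0.85 with an estimated correlation). That count was 118, 69, 170 and 84 without the same mice in turn. Cluster T21, high in Hspa1a, held 11.2% of this class in CTRL and 26.5% in Trpv1-ADC mice.

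CD8 T cell-like cells of Trpv1-ADC mice had more Ccl4, a chemokine of effector T cells (log2 fold change 1.81 ± 0.19, edgeR adjusted p = 3.2e-06), Hsph1 (1.51 ± 0.20, 0.0066) and Atf3 (1.04), and less Myo1h (-3.06). In this class 13 genes were higher and 5 lower of 8457 (560 at raw p under 0.05). The count of 18 fell to 4 with DESeq2, 5 with cells drawn down, 5 with only tag doublets removed, 10 with the stricter cell filter and 11 at Leiden resolution 2. It was 24 with the ratio rule for tags and 67 without the low-count filter, and rose in each fit that left out a mouse. Atf3 was lost without CTRL 1 (0.0901). Mixed effector T cell-like cells, of CD4 and CD8 T cells with type 1 and type 3 markers, had lower Icos (-0.83 ± 0.16, 0.00135), a co-stimulator, Il18r1 (-0.92), Ramp3 (-0.93 ± 0.19, 0.0033), Rgs1 (-0.82) and Plac8 (-2.36), and higher Klf2 (1.12), which keeps T cells recirculating, and Nr4a1 (0.93). Here 12 were higher and 40 lower of 5149 (456 at raw p under 0.05). The count of 52 fell to 21 with DESeq2, 17 with cells drawn down, 22 with the stricter cell filter, 24 at Leiden resolution 2 and 35 with the ratio rule for tags. It was 115 with only tag doublets removed and 84 without the low-count filter, and also rose without Trpv1-ADC 1. Icos, Il18r1, Klf2 and Nr4a1 lost their calls without CTRL 1 (0.146, 0.209, 0.0612 and 0.26), and Rgs1 without CTRL 2 (0.0872). In CD4 T cell-like cells only AA465934 passed (3.01, 0.00563) of 9586 genes (593 at raw p under 0.05, DESeq2 0), against 54, 244, 60 and 39 without CTRL 1, CTRL 2, Trpv1-ADC 1 and Trpv1-ADC 2. The values there were -0.68 ± 0.14 for the survival receptor Il7r (0.329) and -3.20 ± 0.52 for the chemokine Cxcl13 (0.139). Heat shock genes rose as a list in these 3 classes (medians 0.82, 0.65 and 0.81, adjusted p = 0.85 with an estimated correlation).

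Few genes passed the test in naive T cell-like cells. In naive CD4 cells the kinase gene Prkca fell by 0.56 ± 0.08 (edgeR adjusted p = 0.0026) and Odc1, of polyamine synthesis, by 0.56 ± 0.09 (0.0127). Slfn9 rose by 3.01 ± 0.42 (0.0141), a gene 9.74 Mb from Trpv1 on chromosome 11. The rise of Slfn9 was not particular to this class, as both Trpv1-ADC mice lay above in 9 of 9 classes tested. In all 4 genes were higher and 3 lower of 10926 (746 at raw p under 0.05). In naive CD8 cells the small heat shock gene Hspb1 rose by 1.61 ± 0.23 (0.0252) and the non-coding 2610035D17Rik by 0.73 ± 0.11 (0.0334), and 1700034P13Rik fell by 2.72 ± 0.40 (0.0252), with 3 higher and 1 lower of 10662 (662). In both, heat shock genes rose as a list (medians 0.83 and 0.88) and the list of 16 naive and recirculating lymphocyte genes was called lower by camera in both (median -0.10), with 0 members past the test over all genes and 4 lower adjusted over the list alone. These lists had adjusted p values of 0.85 with an estimated correlation, and the naive list was lost without CTRL 2 or Trpv1-ADC 2 in both classes (0.212 and 0.411 in CD4, 0.0805 and 0.298 in CD8) and without CTRL 1 in CD4 (0.0708). Clusters T2 and T6, high in Hspa1a, held 22.5% and 14.2% of the naive CD4 and CD8 classes in CTRL mice against 47.9% and 40.4% in Trpv1-ADC mice, and the small clusters T20 and T17 were led by interferon-induced genes such as Ifit1 and Ifit3. They held 1 and 3 cells of CTRL 1, against 31 and 45 of CTRL 2, 50 and 52 of Trpv1-ADC 1, and 22 and 28 of Trpv1-ADC 2. Prkca was lost without CTRL 1 (0.231) or Trpv1-ADC 2 (0.113), Odc1 without any mouse but Trpv1-ADC 1 (0.0659 to 0.2), Slfn9 without CTRL 1 (0.249), Hspb1 without Trpv1-ADC 2 (0.0658) and 2610035D17Rik without Trpv1-ADC 1 (0.0712). The naive CD4 count was 13, 38, 33 and 3 without CTRL 1, CTRL 2, Trpv1-ADC 1 and Trpv1-ADC 2, and the naive CD8 count 74, 261 and 25 without the first 3.

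B cell-like cells had 14 genes higher and 6 lower of 10570 (945 at raw p under 0.05). In Trpv1-ADC mice Prkca fell by 0.58 ± 0.09 (edgeR adjusted p = 0.0104), the kinase gene Fyn by 0.48 ± 0.08 (0.0117) and the phosphodiesterase Pde3b by 0.43 ± 0.08 (0.0405), and the AP-1 subunit Jund rose by 0.39 ± 0.07 (0.0405). The low-expressed Lrp5, a Wnt co-receptor, rose by 4.56 ± 0.66 (0.0031), and Pole2, a DNA polymerase subunit, fell by 2.53 ± 0.33 (0.00239). Heat shock genes had their largest list median here (1.40), with 0 of 14 past the test over all genes and 1 adjusted over the list alone (adjusted p = 3.07e-26, and 0.85 with an estimated correlation). Prkca, Fyn, Pde3b and Jund lost their calls without CTRL 1 (0.109, 0.255, 0.717 and 0.705), and the count was 89, 353 and 65 without CTRL 2, Trpv1-ADC 1 and Trpv1-ADC 2. Cycling cells joined a lymphoid cluster, T22, that held 46.8% of the class in CTRL and 71.2% in Trpv1-ADC mice, and a myeloid one, A30, that held 53.2% and 28.8%. With different clusters holding most of it, Cd5 and Cd4 of T cells rose by 1.61 and 1.53 and the myeloid Ccl6 fell by 2.93, among 44 genes higher and 34 lower of 6918 (761 at raw p under 0.05). The heat shock list rose (median 0.24, adjusted p = 0.00114, 0.85 with an estimated correlation and 0.0635 without CTRL 1). Cd4 and Ccl6 were lost without either Trpv1-ADC mouse (0.0814 and 0.222 without Trpv1-ADC 1), and the count was 161 without CTRL 1, 228 without CTRL 2 and 46 without Trpv1-ADC 1.

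Over the 16 classes edgeR called 1622 of 129487 gene and class pairs, 744 higher and 878 lower, or 993 when adjusted over all classes together. In each of the 1622 both Trpv1-ADC mice lay on 1 side of both CTRL mice, which passing the test nearly ensures, so it adds no support. Chance gives such a separation for 33.3% of genes, and 35.2% to 54.4% of the tested genes of a class showed it, though genes of the same mice do not vary independently. DESeq2 called 795, of which 608 were shared, and the fit without Trpv1-ADC 1 called 3470. Hspa1a and Hsph1, chaperones of the heat shock response, were above in both Trpv1-ADC mice in 16 of 16 classes (called in 4 and 6), with median log2 fold changes of 1.66 and 1.38. AA465934, a transcript at chromosome 11, 83291699 to 83294632 (mm10, plus strand), was above in 14 of 14 classes and called in 11, with a median of 2.67. Ramp3 was below in 13 of 16 and called in 3. Of those calls of AA465934, that in mixed effector T cells was lost without CTRL 2 (adjusted p = 0.0652) or Trpv1-ADC 2 (0.747), and that in monocyte-like cells without CTRL 1 (0.0741), CTRL 2 (0.15) or Trpv1-ADC 2 (0.0743).

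**Figure D3:**
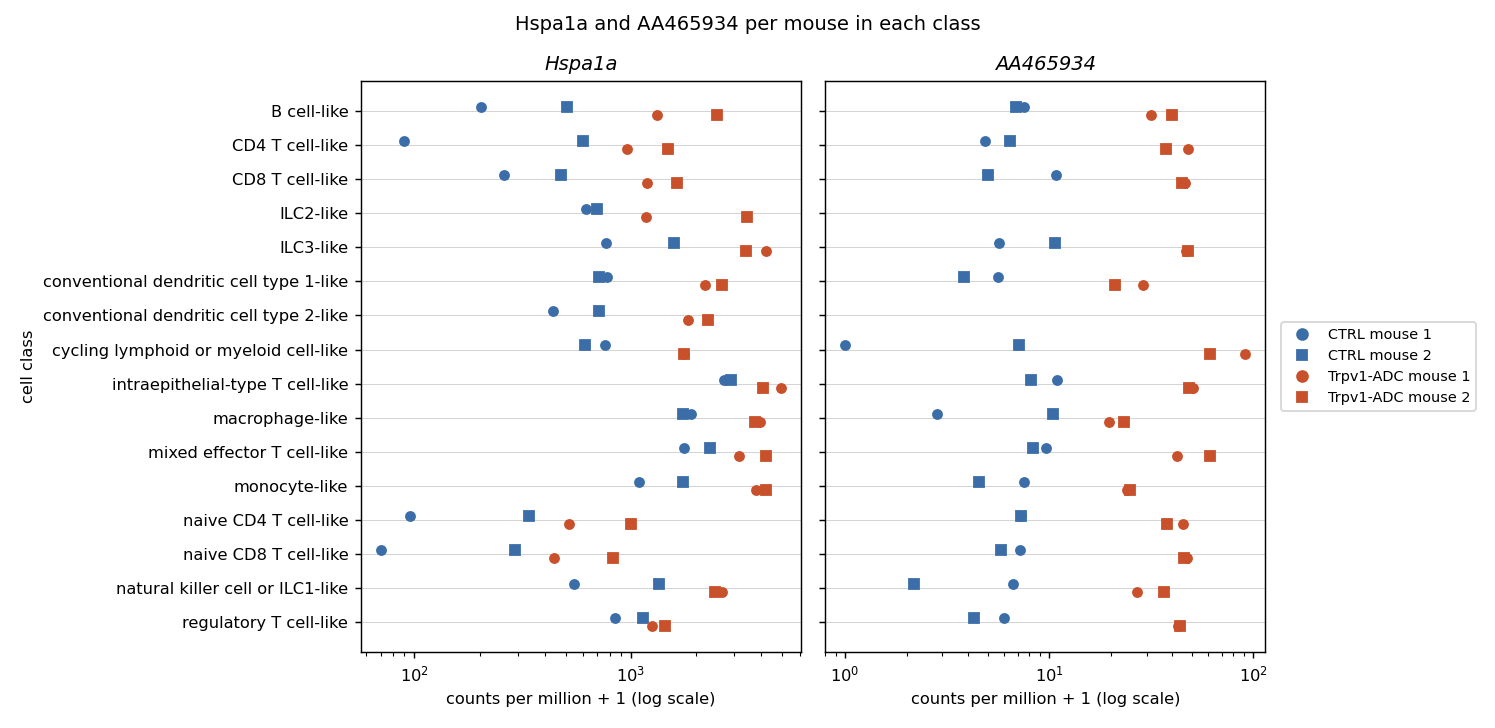
CPM (normalised counts) plus 1 of Hspa1a and AA465934 in each class and mouse, on a log axis. Both Trpv1-ADC mice lay above both CTRL mice in 16 of 16 classes for Hspa1a and in the 14 classes with AA465934 tested. In B cell-like cells Hspa1a stood at 203 and 506 CPM in CTRL 1 and CTRL 2.

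By list and class, camera called 91 of 408 tests, 46 up and 45 down, with 0 differing in sign between median, mean and test. With an estimated correlation 0 held (lowest adjusted p = 0.85, lowest raw p = 0.0179), and fry, which tests whether a list moves one way, called 0. With an estimated correlation camera has only the degrees of freedom of the 4 mice, so after adjustment over 408 tests hardly any list could pass. Its adjusted p of 0.85 was the lowest value of each list alike and does not tell the lists apart. The preset correlation of 0.01 takes list members as nearly independent, so small p values from it do not measure the spread between mice. Heat shock genes rose in 16 of 16 classes, with medians from 0.20 to 1.40. For type I interferon genes a rise was called in 10 classes, but without CTRL 1, the mouse with few cells in the interferon-led clusters, a rise was called in 3 classes and a fall in 3, among them naive CD4 (camera adjusted p = 5.91e-04) and naive CD8 cells (3.11e-18). Interferon gamma genes rose in 2 classes, in 10 without CTRL 2 and in 5 without Trpv1-ADC 1, and were called lower in 4 without CTRL 1. Immediate early genes rose in 8, lymphocytes mostly, and fell in 3, macrophage-like, type 1 dendritic and cycling cells, with 5 rises without CTRL 1 and 5 falls without Trpv1-ADC 1. The cAMP and CREB genes fell in 7 of 16 classes, as did the regulatory T cell genes in 4 and MHC class II genes in 4. Antigen receptor signalling rose in 2 and fell in 3. Falls were also called for cell cycle genes in 3 classes, and in 2 each for germinal centre, chemokine, type 1, type 2 and type 3 genes. Such small counts moved without single mice, among others to 6 for chemokines without CTRL 1, 4 for germinal centre genes without Trpv1-ADC 1, and 0 for type 1 and type 3 genes without CTRL 2. Antimicrobial genes fell in cycling cells. Hypoxia genes were called lower in ILC2-like cells only, a call lost without CTRL 1 (0.0603), CTRL 2 (0.15) or Trpv1-ADC 1 (0.225), and were called higher in 2 classes without CTRL 2 and in 1 without Trpv1-ADC 1. Rises also appeared for inflammatory myeloid genes in 1 class without CTRL 2 and 2 without Trpv1-ADC 2, and in 1 class for antimicrobial and type 2 genes without CTRL 2, for antimicrobial genes without Trpv1-ADC 2, for MHC class II and type 3 genes without Trpv1-ADC 1, and for regulatory T cell genes without either Trpv1-ADC mouse. Plasma cell secretory and naive lymphocyte genes rose in 1 and fell in 2 each. Of the lists that track RNA quality, ribosomal protein genes rose in regulatory T cell-like, monocyte-like, macrophage-like, ILC2-like, ILC3-like and cycling cells and fell in CD4 and naive CD8 cells (medians -0.13 to 0.29), and mitochondrial transcripts fell in CD4 and naive CD8 cells (medians over all classes -0.20 to 0.08). The ribosomal calls were lost in ILC2-like cells without CTRL 2 (0.808) or Trpv1-ADC 2 (0.981), in ILC3-like cells without CTRL 1 (0.0855), in macrophage-like cells without Trpv1-ADC 2 (0.114), and in cycling and naive CD8 cells without any mouse but Trpv1-ADC 1 (0.107 to 0.943, the last downwards, in cycling cells without Trpv1-ADC 2), and the mitochondrial ones in CD4 cells without CTRL 2 (0.92) and in naive CD8 cells without any mouse but Trpv1-ADC 1 (0.174 to 0.398). Mitochondrial transcripts were called higher in 1 class without CTRL 1 and lower in 4 without Trpv1-ADC 1. Called in 0 classes with all 4 mice were IgA switching, TGF-beta and retinoic acid, resident macrophage and neuropeptide receptor genes, and markers of free RNA from epithelium and plasma cells, while markers of blood and granulocytes had too few tested members. With a mouse left out, calls appeared for these tested lists, except neuropeptide receptors and epithelium.

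Receptors for neuronal signals were spread over the immune classes. Of 34 such genes, 16 reached 10 CPM in a class. Ramp3 was highest in CD4 T cell-like cells (735 ± 226 CPM, SD over 4 mice), Htr7, a serotonin receptor and a leading gene of its cluster, in type 1-like dendritic cells (438 ± 99.5), and P2rx7 in macrophage-like cells (262 ± 254), with group means of 77.0 in CTRL and 446 in Trpv1-ADC mice (not past the test, adjusted p = 0.0513) and, in CTRL mice, a level as high in mixed effector T cells (77.1). The CGRP receptor gene Ramp1 was highest in ILC3-like cells (155 ± 31.6). Calcrl stood at 139 ± 62.3 in ILC2-like cells, with group means of 87.7 in CTRL and 190 in Trpv1-ADC mice (not past the test), and at 113 ± 15.2 in naive CD4 cells, the highest class in CTRL mice (104). Vipr1 and Vipr2, receptors of vasoactive intestinal peptide, peaked in naive CD4 (43.6 ± 7.18) and ILC2-like cells (36.5 ± 28.4, from 5.59 in CTRL 2 to 69.0 in Trpv1-ADC 1), and the neuromedin U receptor gene Nmur1 in ILC2-like cells (22.7 ± 2.44). The substance P receptor gene Tacr1 and Trpv1 itself had 1 UMI each in their highest class. Classes were ranked by means over both groups and were not tested against each other.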

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

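All tests of explanations in this part were chosen after the results were seen. Some genes moved in opposite directions in different classes, and the differences between classes were not tested. Areg had log2 fold changes of -1.80 in ILC3-like, -2.04 in monocyte-like, -1.45 in cycling and -0.61 in regulatory T cell-like cells, against 2.43 in type 1-like conventional dendritic cells. Ccl5 stood at 1.82 in macrophage-like and -0.84 in regulatory T cell-like cells, an opposition that was gone at Leiden resolution 2 (-0.16 in macrophage-like cells) and with only tag doublets removed (-0.014). Nr4a2 stood at -1.18 in type 1-like dendritic cells and 0.75 in regulatory T cell-like cells. Calls of Areg were lost in monocyte-like cells without CTRL 1 (adjusted p = 0.183), in regulatory T cell-like cells without CTRL 2 (0.274) or Trpv1-ADC 2 (0.0833) and in cycling cells without CTRL 2 (0.0692), Trpv1-ADC 1 (0.204) or Trpv1-ADC 2 (0.0881), and in regulatory T cell-like cells also that of Nr4a2 without Trpv1-ADC 2 (0.161) and that of Ccl5 without CTRL 1 (0.388), Trpv1-ADC 1 (0.171) or Trpv1-ADC 2 (0.133). In the hashtag matrix, tags that the labels give to no mouse had counts above the floor of 3: HT2 5743, HT4 7137, HT5 193, HT6 6550, HT8 173, HT10 90, HT11 557, HT12 1997 and HT13 6. The tags assigned to mice had 8047689 (HT1), 4261397 (HT3), 2011933 (HT7) and 3391892 (HT9).

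AA465934 was higher in both Trpv1-ADC mice in 14 of 14 classes. Free RNA in the shared run would reach the cells of all mice alike, yet the group means differed by a ratio of at least 3.64 in every class tested, which argues against it. The gene lies 10.1 Mb from Trpv1 on chromosome 11. Slfn9, 9.74 Mb from Trpv1, was also higher in both Trpv1-ADC mice in 9 of 9 classes tested (median log2 fold change 1.37). With AA465934 and heat shock genes left out, genes shifted across classes were more frequent within 20 Mb of Trpv1 than elsewhere. They were 3 of 271, Slfn9, Ints2 and Rnf43, against 19 of 7750 (one-sided Fisher exact p = 0.0365). The p was 0.3402 for 10 Mb, 0.0262 for 30 Mb and 0.0919 for 20 Mb with heat shock genes kept, so DNA linked to a Trpv1 allele that differed between the groups may be a candidate explanation but stays open, as the labels name the strains Trpv1-WT.B6 and Trpv1-Cre.B6 but not by group. A response to neuron activation stays open too: a difference in 14 classes is compatible with either, and no mouse separates them.

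Heat shock transcripts were higher in Trpv1-ADC mice, with Hspa1a above in 16 of 16 classes. Free RNA would level the mice of 1 run, so a separation in 16 classes argues against it. In the 9 classes made of a single cluster a change in cluster makeup does not account for it, with a median log2 fold change of 1.69 (lowest 0.837). For classes of several clusters it stays open: T2, T6 and T21, high in Hspa1a, held 22.5%, 14.2% and 11.2% of their classes in CTRL mice. They held 47.9%, 40.4% and 26.5% in Trpv1-ADC mice. Hspa1a stood at 1165 CPM in T2 against 168 in T0, the other large naive CD4 cluster. It stood at 1121 in T6 against 170 in T1, the other large naive CD8 cluster. Larger shares of T2 and T6 may therefore be the heat shock rise itself and are not a separate cause. T9, also high in Hspa1a, went the other way, from 41.8% of regulatory T cell-like cells in CTRL to 24.5% in Trpv1-ADC mice. For handling of each mouse before the tags were mixed the values are divided: CTRL 2 stood at 2.49 times the Hspa1a level of CTRL 1 in B cell-like cells, but the CTRL mice were close in macrophage-like cells (1897 and 1741 CPM). The groups overlapped in 0 of 16 classes, where handling unrelated to group was to give overlap in most. Since the classes of a mouse share its handling, the 16 classes are not separate evidence. Chance alone parts 2 from 2 mice with a share of 33.3%, so the count cannot decide. Handling, whether or not it followed the groups, and neuron activation cannot be told apart with 2 mice per group. A strain difference between the groups stays open, untested.

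Intraepithelial-type T cells, monocyte-like and neutrophil-like cells had lower shares, and naive T cells higher ones, in Trpv1-ADC mice, without passing the test, while macrophage-like shares overlapped (4.00% and 2.01% in CTRL, 2.80% and 1.67% in Trpv1-ADC mice). Tag calls that lose more CTRL cells would shrink the difference under the ratio rule, which returns 1254 tag doublets to a mouse, 820 of them to CTRL 1. The intraepithelial-type share then had a log2 fold change of -1.15, against -1.20, which argues against it. More lymphoid tissue of the gut wall in the Trpv1-ADC samples would raise B cells with naive T cells. The naive CD8 and B cell-like log2 fold changes differed by 1.83 times the SE of their difference, which leaves this open beside neuron activation and a strain difference between the groups, both untested.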

How the results depend on the processing

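Tests within single clusters, clustering without interferon, heat shock and immediate early genes, and the naive cells left out of a denominator were chosen after seeing the data. The causes of the moves below were not tested, except that single clusters, drawn-down cells and left-out mice hold fewer cells or mice. Class shares (0 called) had 2 under the strict filter, 7 without Scrublet, 4 with mouse number as a block and 0 to 1 with a mouse left out. The regulatory T cell share of CD4 T cells (-6.24 points) was -1.65 over all T cells, -1.58 by the Foxp3 rule, -13.6 without naive cells and -7.67 to -4.81 with a mouse left out. Genes called (1622) were 795 with DESeq2 (608 shared), 3643 without the low-count filter (1519 shared), 2649 with the block (1516 shared) and 1557 to 3470 with a mouse left out (748 and 1253 shared). Mouse numbers did not pair the mice, with a median correlation of deviations of -0.0009. Intraepithelial-type calls (928) were 482 drawn down, 306 with DESeq2, 528 in T4 alone, 181 in T7 alone and 368 to 1282 with a mouse left out. Regulatory T cell calls (114) were 32 with DESeq2, 43 under the tag ratio rule, 33 under the strict filter, 36, 32, 15 and 0 in T8, T9, T13 and T14 alone, and 65 to 119 with a mouse left out. Lists (91) and classes with a heat shock (16) or type I interferon rise (10) came to 0 with an estimated correlation and with fry, and lay at 80 to 112, 13 to 16 and 3 to 13 with a mouse left out. Reversed values were the B cell-like share (-0.049 without CTRL 1, -0.11 without Trpv1-ADC 1, highest 0.25), Fn1 in cycling (2.48) and Cxcl3 in macrophage-like cells (1.12) without Scrublet, and Ccl5 in macrophage-like cells (-0.16 at resolution 2, -0.014 without Scrublet). Others were Olfr1369-ps1 in mixed effector cells (0.052, clustered without state genes) and Gata3 (0.11 without CTRL 1, lowest -0.57) in regulatory T cell-like cells. Of the named genes, DESeq2 size factors left 333 on their side of the threshold, weakened 11 and reversed 0, and DESeq2, where it gave an adjusted p, left 171, weakened 46 and reversed 0. Those left include values called in neither fit. Of named genes called in the main fit, DESeq2 called 8 of 34 in regulatory T cell-like and 29 of 58 in intraepithelial-type cells. Over the classes this ran from 0 of 1 in CD4 T cell-like to 7 of 7 in natural killer cell or ILC1-like cells. Weakened were 123 without CTRL 1, 95 without Trpv1-ADC 2, 113 with cells drawn down and 102 without Scrublet. Of the 16 classes, the gene count moved by over 1.5 times in 14 without the low-count filter, 12 each with cells drawn down and with the block, 11 with DESeq2, 9 without Scrublet, 7 under the tag ratio rule 6 each at resolution 2 and under the strict filter, 5 without robust fitting, and 11 to 14 with a mouse left out. Of simulated 1.5-fold changes 1.49% to 26.2% were recovered, so that most changes of that size would be missed in each class.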

Other observations

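No test of an explanation is added in this part, and its genes and lists are those fixed before the data were examined. In CD8 T cell-like cells the 23 regulatory T cell genes tested fell as a list (median log2 fold change -0.38, camera adjusted p = 3.57e-06, and 0.85 with an estimated correlation): 1 member fell, and 6 fell adjusted over the list alone. ILC3-like cells had 18 type 1 and cytotoxic genes lower as a list (median -0.36, adjusted p = 0.00755, 0.85 with an estimated correlation and 0.0728 without CTRL 2), with 1 called. In type 2-like conventional dendritic cells, 15 MHC class II genes, which present antigen to CD4 T cells, fell as a list by a median of -0.21 (adjusted p = 6.33e-04, 0.85 with an estimated correlation and 0.123 without CTRL 2) with 0 called. B cell-like cells had 22 immediate early genes higher as a list (median 0.32, adjusted p = 1.84e-12, and 0.85 with an estimated correlation), 1 called and 10 adjusted over the list alone. The heat shock list rose beside each of these, with medians of 0.82, 0.95, 1.10 and 1.40 (adjusted p = 0.85 with an estimated correlation).

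In cycling cells, Il22, the epithelial defence cytokine, was at least 9.01-fold lower and Il1rl1, the interleukin 33 receptor, at least 10.1-fold lower in Trpv1-ADC mice, in which neither had a count (floor of 3 counts over the group). These falls rest on 34 counts of Il22 and 38 of Il1rl1 in the CTRL mice, in a class of 25 to 34 cells per mouse. The lymphoid cluster held 46.8% of the class in CTRL and 71.2% in Trpv1-ADC mice. The call of Il1rl1 was lost without CTRL 1 (edgeR adjusted p = 0.153) or Trpv1-ADC 2 (0.0673), and that of Il22 without Trpv1-ADC 1 (0.075) or Trpv1-ADC 2 (0.098), while Il22 was not tested without CTRL 2. Oprm1, the opioid receptor, rose in intraepithelial-type T cell-like cells by 1.05 ± 0.29 (edgeR adjusted p = 0.0348), a call lost without CTRL 1 (0.0821), CTRL 2 (0.268) or Trpv1-ADC 2 (0.123).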
